A study of Homo sapiens with 11 samples.

How the data were processed

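RNA from formalin-fixed, paraffin-embedded primary cutaneous melanomas was measured in 11 samples, 6 with and 5 without ulceration, 1 per patient. Per the labels' protocols, RNA was isolated from tissue scrolls with a kit for fixed tissue, quantified by fluorescence, and loaded in an amount set by the share of long RNA fragments, more RNA for more degraded samples. It was then hybridised to a NanoString nCounter tumour signalling panel. The study also measured microRNA, which was not analysed here.

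The deposited values are scores in the sense of normalised counts rounded to whole numbers, 1 column per sample. The 6 positive control probes sum to between 25680 and 25682 in each of the 11 samples, which raw counts would not do, so counts were scaled to the positive controls before deposit. The sums over genes and over reference genes differ between samples, so no scaling to reference genes was applied, and negative control probes keep their values, so no background was subtracted. The software, its version and the steps of this scaling are not given in the sources used here. Because fixed tissue yields RNA of varying integrity and the loaded amount varied by protocol, the values as deposited mix expression with the amount of usable RNA. Signal over background limits the precision: the negative controls averaged between 9.38 and 15.5 per sample, and genes near that level carry little information. The number of samples limits the precision of all other genes.

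The table has 780 gene probes, 6 positive and 8 negative controls. Probe names were set against the symbols of the RefSeq table supplied (used for names only): 778 of 780 matched a current symbol, 2 matched through an older one, and 5 probes read several near-identical genes and keep their joint name. No genome build applies to these probe values, so no coordinates are given. No sample was left out, and 0 columns were unused.

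A gene was tested if its value was at least 20 in at least 5 samples, which kept 739 probes and left out 41. Differences were tested on log2(value + 1) with limma 3.58.1 (lmFit and eBayes, no trend, not robust; R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The pseudocount of 1 understates differences of genes near background. The planned design for scaled values was used; a count model was planned only for raw counts and was not run, because the values are not raw counts. Genes were also tested 1 by 1 with an exact permutation test over all 462 assignments of the 11 samples to groups of 6 and 5, for which the smallest possible p is 0.0022. Each sample comes from another patient, so p-values measure the spread between patients' tumours. The labels give no batch, and replicate numbers only name samples and pair none.

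In all, 39 gene lists were fixed before the data were examined, covering cell types of a skin tumour and signalling pathways, with a list of reference genes used for scaling. camera in limma (preset correlation between genes 0.01) tested the 31 lists with at least 5 tested members against the other genes, with Benjamini-Hochberg adjustment over the lists. It was repeated with the correlation estimated from the data, and fry tested whether each list moves in 1 direction on balance. List scores, the mean log2 value of the tested members per sample, were compared for the 37 lists with at least 3 tested members by the exact permutation test. Scores relative to the mean of all tested genes were added after seeing the data. The reference genes themselves, 20 of them tested, stood at a mean log2 difference of -0.20 (exact permutation p = 0.545).

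Genes named in the text follow a rule set beforehand: up to 15 genes past the threshold in each direction; since fewer than 10 passed, the 10 with the smallest unadjusted p in each direction; and up to 4 members with the smallest unadjusted p in each list described. Some genes that the rule takes are not reported here.

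Each result was recomputed with no filter and with a filter at 50, with each sample centred on its median gene or on its reference genes, with quantile normalisation, with a pseudocount of 10, with limma's trend and robust options, with sample weights (arrayWeights), with the level of the keratinocyte and epidermis list as a covariate, and without each sample in turn. The tests were tried on simulated data: 20 data sets with the real genes' means and spread, in which 200 of 739 genes were changed by known folds. As deposited, 5.14% of the calls in these simulations were false, and with reference-gene scaling 48.2% of genes changed 2-fold were recovered. To gauge chance, the tests were repeated on 100 splits of the 11 samples into groups of the same sizes, the real one included.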

Results

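RNA was measured in archived, formalin-fixed tissue of 11 primary cutaneous melanomas, 1 sample per patient. Histology had found ulceration, a break in the epidermis over the tumour, in 6 of them and none in the other 5. A hybridisation and counting assay (NanoString nCounter) read 780 gene probes of a tumour signalling panel, with 6 positive and 8 negative control probes. The deposited values are probe counts scaled to the positive controls, so they still carry differences in the amount of usable RNA between samples. The sum over all gene probes ranged from 514225 to 1450098 per sample, a 2.82-fold span. It averaged 859870 ± 285669 in ulcerated tumours (SD, n = 6) and 1003308 ± 386993 in non-ulcerated tumours (SD, n = 5; two-sided exact permutation p = 0.556). The geometric mean of the reference genes was 752 ± 179 in ulcerated and 911 ± 377 in non-ulcerated tumours (exact permutation p = 0.545). Negative control probes averaged between 9.38 and 15.5 per sample, against a median gene value between 195 and 686.5. Between 654 and 747 of the gene probes per sample read at least 20, and 739 probes reached that level in at least 5 samples and were tested. Below, group values are means ± SD over n = 6 ulcerated and n = 5 non-ulcerated tumours, and differences are log2(value + 1) of ulcerated minus non-ulcerated tumours with their standard error.

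The comparison asks which of the panel's genes differ in expression between melanomas with and without ulceration. By unadjusted p, the first genes with higher values in ulcerated tumours were THBS1, ADM and FPR1, and those with lower values included DLL3, FZD8, CD28 and PPAN, but none of the 739 genes passed the adjusted threshold. THBS1, which encodes the matrix glycoprotein thrombospondin-1, read 6147 ± 4197 in ulcerated and 1716 ± 1139 in non-ulcerated tumours, 3.33-fold higher (log2 difference 1.74, SE 0.56). ADM, the vasodilator peptide adrenomedullin, read 690 ± 367 against 264 ± 149 (1.42, SE 0.49). FPR1, a formyl peptide receptor of neutrophils and monocytes, read 201 ± 65 against 97.8 ± 46.4 (1.09, SE 0.41). After each sample was scaled to its reference genes, 6 of 6 ulcerated tumours lay above the non-ulcerated median for each of these 3 genes. IL6, the inflammatory cytokine, read 406 ± 504 against 68 ± 43 (1.65, SE 0.85; 0.79 with sample weights), with the wide spread of the ulcerated group in its error. The next genes in order of unadjusted p were the Hedgehog transducer SMO (1.06), FOLH1 (0.99), the myosin light chain MYL9 (0.95), the phosphatase DUSP6 (0.64), caveolin-1 CAV1 (0.72) and lipocalin-2 LCN2 (1.49, and 0.78 without non-ulcerated replicate 3).

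On the lower side, DLL3, a Notch ligand, read 115 ± 72 in ulcerated against 576 ± 698 in non-ulcerated tumours (log2 difference -1.77, SE 0.68). CD28, the costimulatory receptor of T cells, read 142 ± 85 against 365 ± 231 (-1.29, SE 0.56), and the Wnt receptor gene FZD8 read 27 ± 9 against 73 ± 45 (-1.19, SE 0.50). After reference-gene scaling, 6 of 6 ulcerated tumours lay below the non-ulcerated median for DLL3, CD28 and FZD8. PPAN had a log2 difference of -1.17, the lymphocyte receptor KLRG1 of -1.42, the TNF receptor adaptor TRAF1 of -1.13 and ABI1 of -0.88. SORD, sorbitol dehydrogenase, stood at -1.06 and CCND1, cyclin D1, at -0.99.

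**Figure D1:**
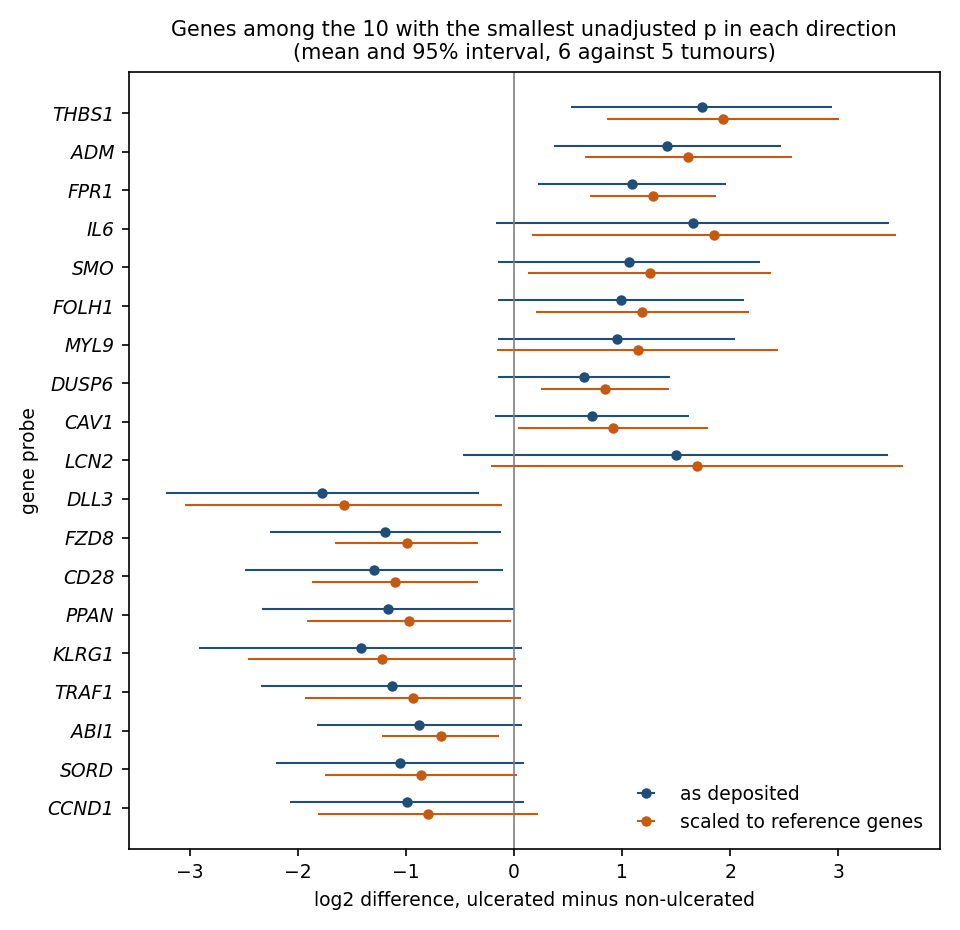
Log2 difference (ulcerated minus non-ulcerated) of the genes named in the text from the 10 with the smallest unadjusted p in each direction, with 95% intervals, for the deposited values and after scaling to the reference genes. THBS1 lies at 1.74 and 1.93, and DLL3 at -1.77 and -1.58, and no gene passed the adjusted threshold under either scaling.

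limma called 0 genes higher and 0 lower at an adjusted p of 0.05, and the lowest adjusted p was 0.966. At an unadjusted p under 0.05, limma gave 3 higher and 5 lower genes, 8 in all, where 36.95 would be expected by chance. The exact permutation test per gene gave 0 genes after adjustment and 12 before it. Its smallest possible p is 0.0022, so a few genes alone could not pass adjustment over 739 genes, and its 0 adds little to limma's. Most genes read lower in the ulcerated group as deposited: 584 of 739 had a lower mean log2 value, and the median log2 difference over all genes was -0.28. Scaling each sample to its reference genes moved this median to -0.08, centring on the median gene to 0.04 and quantile normalisation to -0.02. With reference-gene scaling, limma again called 0 genes, with 15 higher and 12 lower before adjustment, and FPR1 had the lowest adjusted p, 0.322, at a log2 difference of 1.29 (SE 0.27). THBS1 then stood at 1.93 (SE 0.49), ADM at 1.61 (SE 0.44) and DUSP6 at 0.84 (SE 0.27). The median 95% interval reached 1.12 log2 units to either side as deposited and 0.82 after reference-gene scaling. In simulated data with this spread, 200 of 739 genes were changed at once. limma recovered 17.7% of genes changed 2-fold, 73.4% of those changed 4-fold and 93.7% of those changed 8-fold as deposited. After reference-gene scaling it recovered 48.2% of genes changed 2-fold and 85.8% of those changed 4-fold. With fewer changed genes the adjustment is stricter, so these shares overstate the recovery of a few changed genes.

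Grouped by the gene lists fixed before the data were examined, neutrophil genes stood higher in ulcerated tumours relative to the rest of the panel. All 6 tested neutrophil genes had a higher mean log2 value there, by 0.56 on average as deposited and 0.76 after reference-gene scaling, and 0 of 6 passed the gene test over all genes or adjusted over the list alone. Beside FPR1, the list held the calgranulin gene S100A12 (1.04, SE 0.92), the G-CSF receptor gene CSF3R (0.36, SE 0.49) and the probe FCGR3A/B (0.68, SE 0.51), which reads an Fc receptor of natural killer cells and macrophages together with its neutrophil paralog. S100A12 had the higher mean on the log2 scale only, since its linear means were 135 ± 58 in ulcerated and 162 ± 232 in non-ulcerated tumours. With sample weights, S100A12 stood at 0.12, FCGR3A/B at 0.31 and CSF3R at -0.19. After reference-gene scaling, FPR1 passed when adjusted over the list alone (limma adjusted p = 0.0026). camera with a preset correlation between genes called the list higher (adjusted p = 4.3e-05), and adjusted p = 0.988 with an estimated correlation. The list's level minus that of all tested genes was -1.50 ± 0.58 in ulcerated and -2.32 ± 0.51 in non-ulcerated tumours (exact permutation p = 0.043, adjusted p = 0.854).

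T cell genes stood lower in ulcerated tumours. All 27 tested members had a lower mean log2 value, and 26 of 27 lay below the panel's median difference. The list's mean log2 difference was -0.76 as deposited and -0.56 after reference-gene scaling. CD28 was followed by TRAT1 (-1.21, SE 0.77), the signalling adaptor LAT (-1.10, SE 0.64) and CD40LG (-0.93, SE 0.67), and 0 of 27 passed over all genes or adjusted over the list alone. camera with the preset correlation called the list lower (adjusted p = 0.0168), and adjusted p = 0.988 with an estimated correlation. T cell genes moved together between tumours, with an estimated correlation of 0.91, and the list's level relative to all genes, -2.17 ± 0.74 in ulcerated and -1.67 ± 1.09 in non-ulcerated tumours, differed by less than the spread between tumours (exact permutation p = 0.377). B cell and plasma cell genes (5 of 7 lower, mean -0.52) and dendritic cell genes (4 of 5 lower, mean -0.52) were not called (camera adjusted p = 0.949 and 0.730). These shares are near that of all tested genes, 584 of 739 lower as deposited. After reference-gene scaling the means of the 2 lists were -0.32 and -0.33 (exact permutation p = 0.539 and 0.450). The T cell call was lost without ulcerated replicate 4 (adjusted p = 0.0972) or 5 (0.197), or without non-ulcerated replicate 1 (0.332), 2 (0.253) or 5 (0.0730).

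The list of MAPK and RAS signalling components joins the growth pathway that is often mutated in melanoma with stress kinase genes. It read lower in ulcerated tumours in 14 of 14 tested members, by 0.48 log2 units in the mean. Of these members, 12 of 14 lay below the panel's median difference. Among them were the stress kinase gene MAPK8 (-0.81, SE 0.47), RASA1 (-0.85, SE 0.52), which encodes a negative regulator of RAS, and BRAF (-0.52, SE 0.40). None of the 14 passed over all genes or adjusted over the list alone. camera with the preset correlation called the list lower (adjusted p = 0.0137), and adjusted p = 0.988 with an estimated correlation. After reference-gene scaling the list's mean difference was -0.29 (exact permutation p = 0.0065, adjusted p = 0.240). The list's level relative to all genes was 1.04 ± 0.19 in ulcerated and 1.26 ± 0.28 in non-ulcerated tumours (exact permutation p = 0.160, adjusted p = 0.928). The call was lost with median centring (adjusted p = 0.0676), quantile normalisation (0.0612) and sample weights (0.0896), and without non-ulcerated replicate 3 (0.0716). DUSP6, a feedback inhibitor of the pathway whose expression follows its activity, had the opposite sign. Of the 4 tested genes in the MAPK output list, DUSP6 among them, 2 were higher and 2 lower in the mean. CCND1 (-0.99) was 1 of the lower ones, so the output genes gave no common direction.

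Fibroblast and extracellular matrix genes lay above the panel's median difference in 10 of 11 tested members, although only 6 of 11 had a higher mean in ulcerated tumours as deposited and 9 of 11 after reference-gene scaling. The basement membrane collagen genes COL4A2 (0.60, SE 0.41) and COL4A1 (0.54, SE 0.40) and the collagen cross-linking enzyme gene LOX (0.66, SE 0.61) had higher means in ulcerated tumours, LOX at only 0.06 with sample weights. COL6A3 stood at -0.29 (SE 0.57) as deposited, -0.09 after reference-gene scaling, 0.03 with median centring and -0.16 with quantile normalisation. Hypoxia and glycolysis genes lay above the panel's median difference in 13 of 16 members, with a mean log2 difference of 0.03 as deposited and 0.23 after reference-gene scaling. ADM was the only one of the 16 with an unadjusted p under 0.05, and the next in order were EGLN3 (-0.65, SE 0.66), ALDOA (-0.42, SE 0.55) and PFKP (-0.30, SE 0.53). After reference-gene scaling, ALDOA exceeded the non-ulcerated median in 5 of 6 ulcerated tumours, although its mean log2 value stayed lower there, as it was before scaling. PFKP stood at 0.02 with median centring. camera with the preset correlation called both lists higher (adjusted p = 0.0073 for fibroblast and matrix genes, 0.0225 for hypoxia and glycolysis), with adjusted p = 0.988 for both with an estimated correlation. In neither list did a member pass over all genes or adjusted over the list alone. The fibroblast call was lost without non-ulcerated replicate 1 (0.503) or 2 (0.217). The hypoxia call was lost without ulcerated replicate 3 (0.0775) or 5 (0.137), or without non-ulcerated replicate 1 (0.332), 2 (0.155) or 4 (0.0502).

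**Figure D2:**
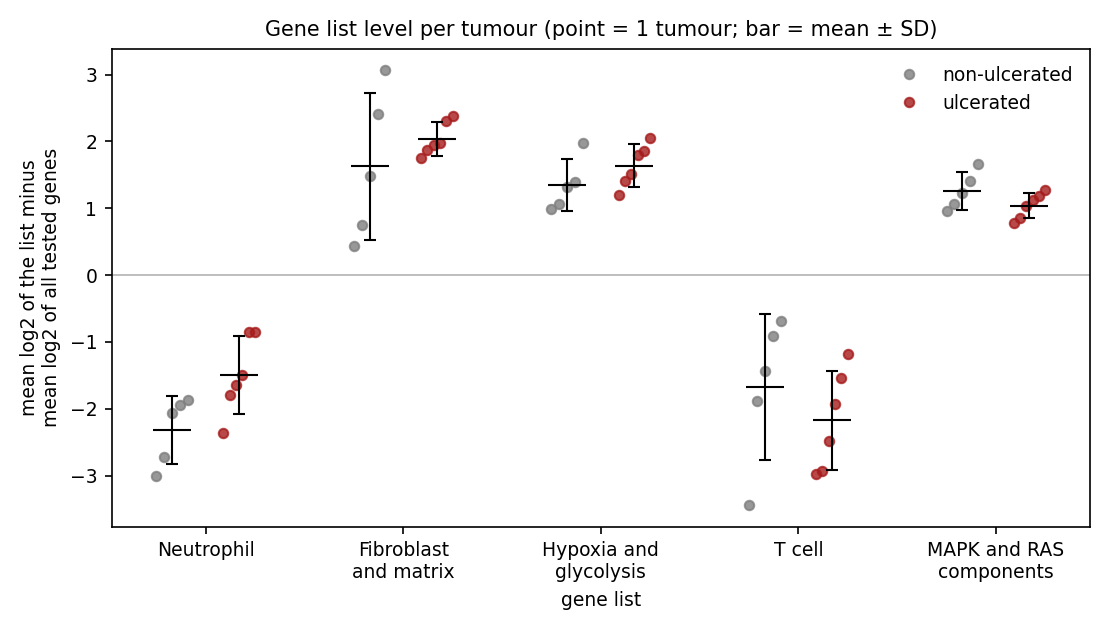
Mean log2 value of a list's genes minus that of all tested genes (vertical axis, log2 units) in each tumour, for the 5 lists called with the preset correlation, with mean and SD per group. The neutrophil level averages -1.50 in ulcerated (from -2.36 to -0.85) and -2.32 in non-ulcerated tumours (from -3.00 to -1.87), so these groups overlap. In the other 4 lists the groups overlap widely.

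These 5 of the 31 lists tested by camera, 3 higher and 2 lower, were called with the preset correlation only. With an estimated correlation 0 lists were called, and fry, which tests a list against no change and not against other genes, called 0. The exact permutation test of 37 list scores also called 0. This last test could not call 1 list alone, because its smallest possible p, 0.0022, exceeds the threshold once adjusted over 37 lists. In simulations in which the 27 genes of the T cell list alone were lowered 2-fold, the preset correlation called that list in 20 of 20 runs and also 4.75 other lists on average, while the estimated correlation called it in 0 of 20.

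Keratinocyte and endothelial markers were not called. Keratinocyte and epidermis genes were higher in 5 of 10 members (camera adjusted p = 0.130; mean log2 difference 0.10, median -0.07). The wound-associated keratin genes KRT16 (1.12, SE 1.34) and KRT17 (0.94, SE 1.15) had values from 59 to 49159 and from 241 to 83956 over the 11 tumours. Their linear means were lower in ulcerated tumours: 8588 ± 7764 against 11625 ± 21030 for KRT16, and 17036 ± 12333 against 22307 ± 34821 for KRT17. The epidermal laminin gene LAMB3 stood at 0.70 (SE 0.71; 0.02 with sample weights) and EPCAM, near background at 17.8 ± 10.6 against 27.8 ± 17.5, at -0.53 (SE 0.53). Endothelial genes were higher in 3 of 8 members (camera adjusted p = 0.215; mean 0.01, median -0.21), with the vessel-remodelling ligand ANGPT2 at 0.96 (SE 0.60; 0.39 with sample weights), VWF at 0.31 (SE 0.50) and NOS3 at -0.35 (SE 0.48). KDR stood at -0.28 (SE 0.44) as deposited, -0.08 after reference-gene scaling, 0.04 with median centring and 0.02 with quantile normalisation.

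In the melanocyte lineage list, 3 of 5 tested genes were lower in ulcerated tumours (camera adjusted p = 0.949). The receptor kinase gene KIT stood at -1.30 (SE 0.76), the melanosome antigen gene MLANA at -0.96 (SE 0.59), CDK2 at -0.57 (SE 0.57) and BCL2A1 at 0.43 (SE 0.47). MLANA read 11939 ± 10923 in ulcerated and 21154 ± 10339 in non-ulcerated tumours, with at least 4225 in every tumour. All 5 tested type I interferon response genes had a lower mean in ulcerated tumours (camera adjusted p = 0.0892, and 0.0555 after reference-gene scaling): OAS1 (-1.01, SE 0.58), IRF7 (-0.97, SE 0.71), OAS3 (-0.94, SE 0.68) and MX1 (-0.70, SE 0.60) among them. NF-kappaB and inflammatory cytokine genes went both ways, 5 higher and 8 lower of 13 (camera adjusted p = 0.154; mean 0.03, median -0.18). IL6 stood high in this list, while TRAF1, NFKB2 (-0.95, SE 0.55) and TNFAIP3 (-0.81, SE 0.51), an inhibitor of the pathway, stood low.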

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

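Dixon's test was run on the log2 values of the named genes, the levels of the described lists and sample-wide measures such as the gene total, not on the other genes. The 134 tests over groups of 5 and 6 tumours gave 0 extreme samples, where 6.7 would be expected by chance. The tests of the amount of RNA and of unrelated T cell content below were chosen after the result was seen, and the others before.

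For the 0 genes past the adjusted threshold, the splits say nothing, since all 100 of 100 must give at least 0; the highest other split gave 15. Chance could not be excluded for the other counts. The 8 genes at an unadjusted p under 0.05 were matched or exceeded in 69 of 100 splits, with up to 306 in another split, and the 27 genes after reference-gene scaling in 45 of 100, with up to 168. Splits that call many more genes than the real one point to a structure of the samples, whose nature was not tested. The 5 lists called with the preset correlation were matched or exceeded in 70 of 100 splits, with up to 14 lists in another split, and the 5 after reference-gene scaling in 65 of 100, with up to 18.

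Most genes read lower in ulcerated tumours, with a median log2 difference of -0.28 (exact permutation p = 0.459). The amount of usable RNA is a candidate explanation: the reference genes were lower too, and scaling to them brought the median to -0.0842 (exact permutation p = 0.461). A biological lowering of most panel genes stays open as untested.

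T cell genes were lower in 27 of 27 members. Scaling to the reference genes took the list's mean log2 difference from -0.756 to -0.561 with 26 of 27 members still lower. camera's call with the preset correlation held (adjusted p = 0.0044, and 0.933 with an estimated correlation). This scaling moves all genes of a sample alike, so the list's difference from all genes, -0.498, could not change with it. That the call held after this scaling therefore adds nothing on the amount of RNA. An amount that shifts all genes of a sample alike would give no difference from all genes. Such a shift could account for only part of the deposited difference. The remaining difference of -0.561 lay within the spread between tumours (exact permutation p = 0.422), so whether it is more than chance stays open. Differences in T cell content between tumours that are unrelated to ulceration may account for the pattern. The list's level relative to all genes differed with an exact permutation p of 0.377. With so few tumours, this p cannot tell unrelated differences from a lowering tied to ulceration, so unrelated T cell content stays open. Fewer T cells in ulcerated melanomas stays open as a biological explanation that these samples do not resolve.

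Neutrophil genes were higher in 6 of 6 members. With the level of keratinocyte and epidermis genes as a covariate the mean log2 difference went from 0.564 to 0.529, and camera's call with the preset correlation held (adjusted p = 5.7e-05). The covariate was taken from deposited values, so it carries the amount of RNA as well as epidermis. It averaged 9.14 in ulcerated and 9.05 in non-ulcerated tumours, so adjusting for it could move the difference only little. Relative to all genes, the keratinocyte list differed by 0.35 (exact permutation p = 0.528), and this level was not used as the covariate. The test therefore cannot weigh the share of epidermis, which stays open. The neutrophil difference lay within the spread between tumours both without the keratinocyte covariate (exact permutation p = 0.327) and with it (0.333). A second set of 12 genes abundant in neutrophils, chosen before its values were seen, differed by 0.0717 relative to all genes (exact permutation p = 0.781), with LCN2 at 1.49 and a lower mean as deposited for the other 11, such as ITGB2 (-0.45), which other leukocytes express as well. More neutrophils in ulcerated tumours may raise the first list, and the second set neither excludes this nor bears it out.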

How the results depend on the processing

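limma called 0 genes higher and 0 lower under all 22 settings for which each count was recomputed, and the list scores gave 0 calls under all 19. None of the 54 named genes passed the threshold in any of 1180 alternatives; the lowest adjusted p was 0.063, reached by FZD8 and others with sample weights. A count model was not run because the values are not raw counts, and no paired analysis was possible because replicate numbers pair no samples. Signal limits the result most for genes near the negative controls, and most simulated 2-fold differences went undetected as deposited.

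The number of called lists was 5, and lay within 1.5 times of that in 18 alternatives. It was 0 with an estimated correlation, 0 with fry and 0 with reference-gene scaling and an estimated correlation together, a setting chosen after seeing the data. Leaving out 1 sample at a time gave 2 to 9 lists: 2 without non-ulcerated replicate 2, 3 without non-ulcerated replicate 1 and 9 without non-ulcerated replicate 3. With an estimated correlation the adjusted p was 0.988 for the T cell list, the Neutrophil list, the Fibroblast and extracellular matrix list, the Hypoxia and glycolysis list and the MAPK and RAS signalling components list. fry asks another question, whether a list moves in 1 direction on balance and not whether it stands apart from other genes. It gave an adjusted p of 0.999 for the Hypoxia and glycolysis list and 0.971 for the other 4. With reference-gene scaling and an estimated correlation, camera's adjusted p was 0.551 for the Neutrophil, Hypoxia and MAPK lists and 0.933 for the T cell and Fibroblast lists. The MAPK and RAS signalling components list also had a camera adjusted p of 0.0676 with median centring, 0.0612 with quantile normalisation and 0.0896 with sample weights. Over the left-out samples the camera adjusted p ranged from 1.1e-07 to 0.332 for the T cell list, 6.1e-06 to 0.503 for the Fibroblast list, 0.0037 to 0.332 for the Hypoxia list, 0.0054 to 0.0716 for the MAPK list and 1.1e-06 to 0.0025 for the Neutrophil list, the only one that no left-out sample took past the threshold. Fewer samples in the fit are part of these changes, and otherwise the cause was not tested.

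The log2 difference shrank by over 1.5 times under at least 1 setting for 42 of the 54 named genes, 19 of them with sample weights. Its sign reversed for 8 named genes, none called. With median centring, COL6A3 stood at 0.0285, PFKP at 0.0168 and KDR at 0.0410, and with quantile normalisation KDR at 0.0197, as centring removes the panel-wide shift. With sample weights, CSF3R stood at -0.19, KRT16 at -0.17 and KRT17 at -0.10; the cause was not tested. Over the left-out samples, PFKP ranged from -0.617 to 0.0344, VWF from -0.0175 to 0.65, ALDOA from -0.80 to 0.11, COL6A3 from -0.734 to 0.0762, KRT16 from -0.20 to 2.22 and KRT17 from -0.25 to 1.86. The last pair and ALDOA reversed without non-ulcerated replicate 3, VWF without non-ulcerated replicate 1, COL6A3 without non-ulcerated replicate 4, and PFKP without ulcerated replicate 6 or non-ulcerated replicate 5.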

Other observations

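Of 34 tested cell cycle genes, 28 had a lower mean in ulcerated tumours as deposited and 15 after reference-gene scaling. Their mean level after that scaling was 7.87 ± 0.75 in ulcerated and 7.88 ± 0.84 in non-ulcerated tumours on the log2 scale (SD, n = 6 and n = 5; exact permutation p = 0.983), a spread that does not exclude a difference. DNA damage repair genes were lower in 20 of 22 members as deposited, with a mean log2 difference of -0.40, and -0.21 after reference-gene scaling (camera adjusted p = 0.215 and 0.305). All 13 tested epigenetic regulators were lower as deposited and 11 of 13 after reference-gene scaling. Their mean log2 differences were -0.43 and -0.23 (camera adjusted p = 0.118 and 0.131). Their level relative to all genes had an exact permutation p of 0.054 (adjusted p = 0.854). Cytotoxic and natural killer cell genes were lower in 15 of 16 members as deposited and 11 of 16 after reference-gene scaling. Their mean log2 difference was -0.40 as deposited and -0.21 after that scaling, and -0.14 relative to all genes. camera gave them no clear side, higher as deposited and lower after reference-gene scaling (adjusted p = 0.957 and 0.866). After reference-gene scaling, THBS1 passed when adjusted over the list alone in the p53 target list (limma adjusted p = 0.0143) and in the TGF-beta and dedifferentiated melanoma lists (0.0266 in both), and DUSP6 in the MAPK output list (0.038).

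Some genes varied widely between tumours of the same group. After reference-gene scaling, the median gene had a standard deviation within groups of 0.64 log2 units. The genes below were chosen after their values were seen, from a ranking that left out 7 probes of polymorphic immune receptor and HLA genes. The cancer-testis antigen gene MAGEC2 (deposited values from 2, as low as negative controls, to 399), the neural stem cell factor gene SOX2 (6 to 726) and ALDH1A3 (68 to 41502) had standard deviations of 2.58, 2.58 and 2.29 log2 units within groups. The interferon-induced chemokine genes CXCL9 (47 to 9230), CXCL10 (60 to 6042) and CXCL11 (7 to 938) had standard deviations of 2.45, 2.18 and 2.28. Another cancer-testis antigen probe, CTAG1A/B, fell under the filter with a median value of 4 and a highest value of 679.

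THBS1, ADM and FPR1 had the smallest unadjusted p among genes with higher values in ulcerated tumours, and a hypothesis is that they follow 1 shared source of variation between samples. This was tested, by a rule set before the correlations were seen, over the 11 samples with each group centred on its mean after reference-gene scaling, in a family of 3 relations with 100000 permutations within groups. Pearson's r was 0.634 between THBS1 and ADM (permutation p = 0.0548), 0.575 between THBS1 and FPR1 (p = 0.0738) and 0.670 between ADM and FPR1 (p = 0.0379), and the adjusted p was 0.0738 for each of the 3. Spearman's rho was 0.591 (permutation p = 0.0833), 0.409 (p = 0.240) and 0.445 (p = 0.192), with an adjusted p of 0.240 for each. Without the 2 samples farthest from the median of the first gene, r was 0.227, 0.152 and 0.195, so the relation did not hold without those samples. How far it rests on them stays open, because leaving out extreme samples lowers r for any linear relation. The genes may share a source, with a lowest r of 0.575, but no correlation passed the adjusted threshold.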
